A study of Mus musculus with 14 samples.

How the data were processed

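RNA was sequenced from hematopoietic stem cell-enriched mouse bone marrow cells of 14 libraries. The cells were sorted with the SLAM marker scheme, which keeps lineage-negative, Sca-1-positive, Kit-positive cells that lack Flk2 (the receptor encoded by Flt3) and CD48 and carry CD150 (encoded by Slamf1). C57BL/6 mice had received intraperitoneal interleukin-1 beta (IL-1β), an inflammatory cytokine, at 0.5 µg per mouse per day, or phosphate-buffered saline (PBS), for 1 or 20 days. Each library is a biological replicate from cells pooled over 3 to 5 mice, per the series' design text. There are 3 PBS and 3 IL-1β libraries at 1 day, and 4 and 4 at 20 days.

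Per the labels' protocols, SMARTer chemistry for low input amplified the cDNA, Nextera XT libraries were made from it, and a HiSeq2500 read them from a single end. This chemistry does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The submitters' processing notes name Trimmomatic 0.32, STAR 2.4.2a, HTSeq 0.6.1, Cufflinks 2.0.2, Cuffdiff, DESeq2 1.12.3 and the genome build GRCm38.p4, without giving their roles. The annotation and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of raw counts per gene symbol, with whole numbers whose totals differ between libraries. It lists 24833 genes, none with a total under 2 counts. No other normalisation is recorded for these counts. Amplified reads carry no molecular identifiers, so counting intervals and floors cover counting error only.

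The totals run from 21654896 to 29441947 counts per library, so that 3 counts in a single library amount to 0.102 to 0.139 CPM, the usual scaling of counts to a common library total. For a gene without reads in a group, the floor was 3 counts over the summed total of the group's libraries, which is lower in CPM. Replicates of a group were compared before averaging. Over the 18 pairs within groups, chi-square per degree of freedom lay between 11.2 and 81.4, so no pair differed by as little as sampling noise. The library titles fall into 4 naming sets, each with equal numbers of IL-1β and PBS libraries of 1 duration. At 1 day these are "10k" (1 against 1) and "E060216" (2 against 2). At 20 days they are "E061316" (replicates 1 and 2) and an untagged set (replicates 3 and 4). What the tags mean is not stated. Replicate labels shared between groups were checked as possible pairs, and the check is described with the alternatives.

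Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr on the groups (minimum count 10; 15466 genes kept), and the robust quasi-likelihood F-test, two-sided. Benjamini-Hochberg adjustment was applied over the genes tested, with a threshold of 0.05. All 14 libraries entered 1 fit with a term for the naming set and an IL-1β effect for each duration, which left 8 residual degrees of freedom. The biological coefficient of variation was 0.198 in this fit. The difference between the 20-day and 1-day effects was tested as an interaction in the same fit. PBS at 20 days and PBS at 1 day were compared in a fit of group means with 10 residual degrees of freedom, because the naming sets are nested in the durations. Printed CPM values are scaled by the TMM factors, except sums over a list and counting bounds, which use the library totals. The rule below takes 156 genes. Of the 124 genes followed library by library, 105 are among them and 19 were chosen after their values were seen.

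Gene lists (32, for pathways, lineage programs, cell cycle, and markers of other cells that a bone marrow sort could hold) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists with at least 5 measured members. Lists of T and NK cell and of mast cell and basophil genes had fewer members and were not tested. Every list was also tested with an estimated correlation and with fry. When treatment labels were reassigned, camera at the preset correlation still called a median of 9 lists at 1 day and 12 at 20 days. Its adjusted p-values can therefore overstate the certainty of a list's change. Some members belong to more than 1 list, such as Flt3 and Cd52. Genes named in the text come from a rule: per comparison, the 6 largest increases and 6 largest decreases among called genes with the same sign in both naming sets, leaving out predicted genes; up to 3 called members with the smallest p of each list, or the 2 with the smallest p where none is called; and 10 genes named in advance, which are Spi1, Il1r1, Il1rap, Myc, Cebpa, Csf1r, Csf3r, Itgam, Cdkn1c and Cdk6. For the interaction the rule takes the 6 genes with the smallest p. Not every gene the rule takes from the lists is named. The genes outside the rule, chosen after their values were seen, are Tgfbi, Vldlr, Pcp4l1, Hbb-bs, Mcm5, Mpo, Elane, the neutrophil genes Ngp, Ltf, S100a8 and S100a9, and Gbp6, Ms4a6b, Ms4a6c, Cyp26b1, Rarb, Rdh10, Dhrs3 and H2-Ab1; Cyp26b1, Rarb and Rdh10 were followed and are not reported further. Design, lists, rule and most alternatives were fixed before the data were examined.

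Positions are those of GENCODE M21 on GRCm38, matched by symbol; 23086 of the 24833 symbols were found there, and 14615 of the 15466 genes tested.

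The fits were tested on simulated negative binomial counts with the naming sets' mean levels, the libraries' sizes and the genes' dispersions. By each of 3 folds, 66 or 67 genes were changed, drawn from those with a mean of at least 20 counts. Recovery of genes with fewer counts was not measured. At 1 day edgeR recovered 37.3% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 80.3% of those changed 4-fold, with 2 false calls over 15466 genes. At 20 days it recovered 47.8%, 86.6% and 90.9%, with 9 false calls. DESeq2 1.42.0 made 25 and 23 false calls in the same simulations, and limma-voom 6 and 8.

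Alternatives were other scalings (DESeq2 size factors and upper-quartile factors), no filter or a mean of at least 50 counts, DESeq2's Wald test, limma-voom, no naming set term, the replicate label as a block, the libraries of 1 duration or 1 naming set alone, an adjusted p of 0.1, a further limit of 1 on the log2 scale, and leaving out each library in turn. A correction for GC content and exon length and a fit of the E-tagged naming sets alone were added after seeing the data. The fit without IL-1β 20-day replicate 3 was planned as a leave-out, and was singled out after its neutrophil genes were seen.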

Results

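RNA of hematopoietic stem cell-enriched bone marrow cells was counted per gene in 14 libraries from mice given IL-1β or PBS. The 1-day groups held 3 PBS libraries with 21654896, 24489187 and 26959111 counts and 3 IL-1β libraries with 25081569, 26183573 and 27709611. The 20-day groups held 4 PBS libraries with 22318141, 22437885, 25138116 and 29441947 counts and 4 IL-1β libraries with 22469320, 24540822, 27456785 and 28274161. Values below are CPM as mean ± SD over these libraries, or log2 fold changes of IL-1β over PBS ± SE. The log2 fold changes and their Benjamini-Hochberg adjusted p are from edgeR's quasi-likelihood fit, which gives no SE. The SE printed is the absolute log2 fold change divided by the square root of the F statistic. It is approximate, and least reliable for genes with few counts and for very small changes.

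The 1-day comparison addresses the response to acute IL-1β. Of 32 genes of mitosis 31 rose, as did 20 of 37 genes of DNA replication, while genes of the interferon response, antigen presentation and stem cell identity were among those that fell. Ccnb1, which encodes a cyclin that drives entry into mitosis (ENSMUSG00000041431, GRCm38 chromosome 13, 100778650 to 100786570, minus strand), went from 92 ± 8.88 CPM with PBS to 184 ± 23.5 with IL-1β (SD, n = 3 each). H2-Aa, which encodes an MHC class II chain (chromosome 17, 34282744 to 34287823, minus strand), went from 60.6 ± 9.21 to 24.6 ± 4.20 CPM, 2.46-fold lower.

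Of the 32 mitosis genes measured, 31 rose and none fell (32 rose adjusted over the list alone), with a median log2 fold change of 0.86 (camera adjusted p = 9.33e-75, adjusted p = 0.0162 with an estimated correlation). The median was 0.63 in the 10k naming set and 1.03 in E060216. Ccnb1 rose by 1.00 ± 0.11 (adjusted p = 0.00036), and Aurka, a mitotic kinase gene, by 1.00 ± 0.11. Of 37 DNA replication genes, 20 rose (36 adjusted over the list alone), with a median of 0.59 (naming set medians 0.32 and 0.72, camera adjusted p = 3.78e-34, adjusted p = 0.137 with an estimated correlation). Rrm2, which encodes a subunit of ribonucleotide reductase, rose by 0.98 ± 0.11. Among 12 genes of G1 cyclins and kinases, 3 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.38, naming set medians 0.09 and 0.51, camera adjusted p = 3.63e-05, adjusted p = 0.304 with an estimated correlation). Cdk6, a G1 kinase gene (chromosome 5, 3341485 to 3531008, plus strand), rose by 0.66 ± 0.10, and Ccnd2, a D-type cyclin gene, fell by 0.63 ± 0.11. The 74 oxidative phosphorylation genes had a median of 0.31 with no member called (camera adjusted p = 9.55e-12, adjusted p = 0.533 with an estimated correlation).

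Of 35 interferon response genes, 10 fell (17 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 1.45e-10, adjusted p = 0.0759 with an estimated correlation). Ifit1, an antiviral effector gene, fell by 1.10 ± 0.15, and Ifit3 by 2.10 ± 0.33. Of 19 antigen presentation genes, 4 fell (6 adjusted over the list alone, median -0.32, camera adjusted p = 3.24e-07, adjusted p = 0.304 with an estimated correlation), among them H2-Aa (-1.30 ± 0.20) and H2-Eb1 (-1.14 ± 0.25), whose call ended in 5 of 14 leave-out fits. Of 34 stem cell identity genes, 6 fell (10 fell and 1 rose adjusted over the list alone, median -0.30, camera adjusted p = 3.24e-07, adjusted p = 0.0759 with an estimated correlation), among them Pdzk1ip1 (-0.71 ± 0.09) and Sult1a1 (-1.27 ± 0.24, ended in 3 of 14). Of 22 genes of cell cycle inhibitors and quiescence, 4 fell and 1 rose (8 and 2 adjusted over the list alone, median -0.32, camera adjusted p = 0.00901, adjusted p = 0.466 with an estimated correlation). Without either library of the 10k naming set that call was lost (median -0.20, adjusted p = 0.168). Cdkn1c, which encodes a cyclin-dependent kinase inhibitor, fell by 0.54 ± 0.14, a call that ended in 10 of 14 leave-out fits (adjusted p up to 0.293). Cdkn1c was also called lower by edgeR at 20 days, and no leave-out fit ended that call (adjusted p up to 0.0432). Of 24 immediate early and heat shock genes, 4 fell (9 fell and 2 rose adjusted over the list alone, median -0.52, camera adjusted p = 0.000348, adjusted p = 0.472 with an estimated correlation), among them Egr1 (-1.07 ± 0.22), whose call ended in 4 of 14.

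Of 29 genes of the NF-kB and IL-1 response, 5 fell and 2 rose (7 and 3 adjusted over the list alone, median -0.27, camera adjusted p = 0.00147, adjusted p = 0.341 with an estimated correlation). Bcl3, which encodes a nuclear regulator of NF-kB, rose by 0.90 ± 0.16, while Ebi3, a cytokine subunit gene, fell by 0.86 ± 0.12. Mitochondrial transcripts had a median of -0.47 over 10 genes with none called (1 fell adjusted over the list alone, camera adjusted p = 0.00226, adjusted p = 0.53 with an estimated correlation), with naming set medians of 0.04 and -0.65; the call was lost without PBS 1-day replicate 1 (adjusted p = 0.193). Macrophage markers had a median of -1.16 over 11 genes with none called (naming set medians -0.395 and -1.06, camera adjusted p = 0.0142, adjusted p = 0.466 with an estimated correlation), and the call was lost without IL-1β 1-day replicate 2 (adjusted p = 0.072). The remaining 18 lists tested were not called. The PU.1-dependent myeloid list, named for the transcription factor encoded by Spi1, had a median of -0.06 with 1 of 30 members lower, and Spi1 itself had -0.15 ± 0.10 (adjusted p = 0.442). Il1r1, the IL-1 receptor gene, had 1.06 ± 0.29 (adjusted p = 0.0522).

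In all, 672 of 15466 genes changed after 1 day, 389 higher and 283 lower, each with the same sign in both naming sets. The calls rest on these same sets, so the shared sign is nearly given and is no separate replication. By at least 2-fold, 58 rose and 70 fell. By the ranking of fold changes, Tln2 (4.32 ± 0.91), Rcvrn (4.04 ± 0.66), Tmem215 (3.45 ± 0.59), Ttll13 (3.40 ± 0.77) and Prom1 (3.30 ± 0.66) were among the 6 largest increases, and Hesx1 was at least 9.57-fold higher against 3 counts over the PBS group. Syn1 was at least 38.5-fold lower against the same floor, and Fam78b 29.2-fold lower (95% counting interval 9.63 to 144). Without PBS 1-day replicate 1, which holds 85 of its 107 counts, Syn1 was at least 11.9-fold lower. Plet1os fell by 4.18 ± 0.83, Gbp10 by 3.97 ± 0.82, Npas3 by 3.34 ± 0.88 and Gbp4 by 2.31 ± 0.32. Leaving out each of the 14 libraries in turn ended the call in 11 fits for Syn1, 9 for Npas3, 5 for Ttll13, 4 for Tln2, 4 for Gbp10, 3 for Prom1, 2 for Plet1os and 4 of the 13 that tested Hesx1. No leave-out fit ended it for Rcvrn, Tmem215, Fam78b or Gbp4. Chosen after their values were seen, Tgfbi (2.07 ± 0.14, 4.21-fold) and Vldlr (1.73 ± 0.11, 3.31-fold) had the smallest adjusted p named here, 2.3e-06. The count was 228, 329, 331 and 239 without IL-1β replicate 1, IL-1β replicate 2, PBS replicate 1 and PBS replicate 2 of the 1-day groups, 1244 without PBS 20-day replicate 4, and 290 without the naming set term. With upper-quartile factors it was 743, with 344 higher and 399 lower.

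**Figure D1:**
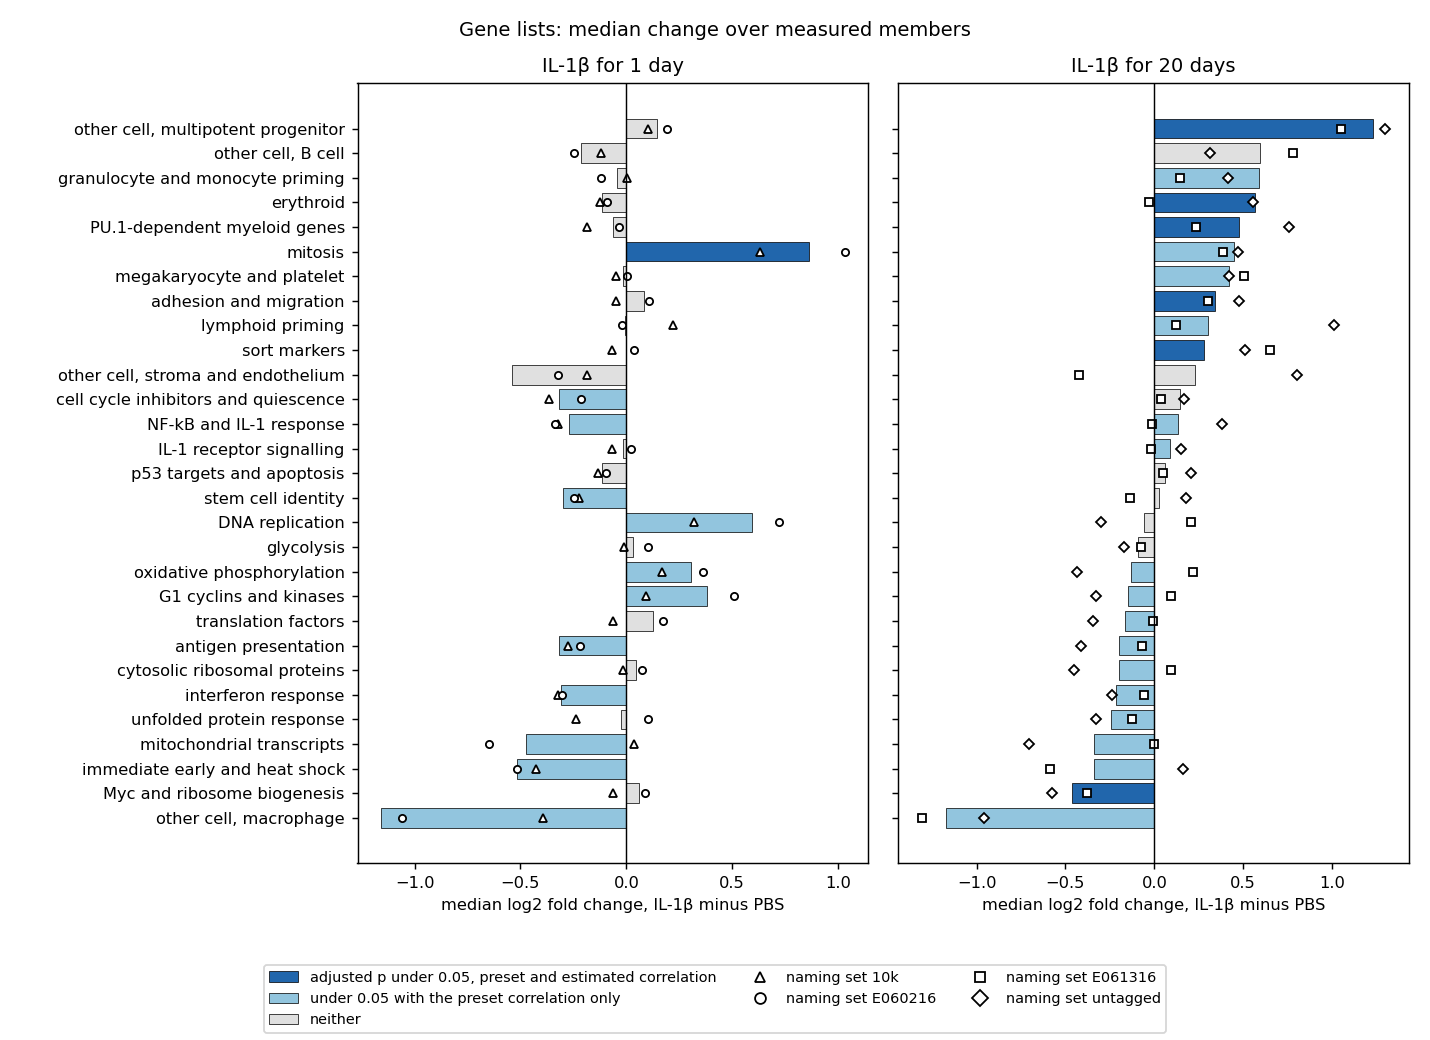
Median log2 fold change of the members of each gene list after 1 day and 20 days (bars), with the medians within each naming set (open symbols); dark blue marks camera adjusted p under 0.05 with preset and estimated correlation, light blue with preset correlation alone, and grey neither. Mitosis had the largest positive median among called lists after 1 day, 0.86, and the multipotent progenitor list after 20 days, 1.23; the neutrophil list is not drawn.

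The 20-day comparison addresses the response to chronic IL-1β. Of 10 multipotent progenitor genes 8 rose (5 without IL-1β replicate 3), as did 13 of 30 PU.1-dependent myeloid genes and 9 of 23 adhesion genes, while 25 of 33 genes of Myc and ribosome biogenesis fell. Itgb2, which encodes the integrin beta chain of leukocytes (chromosome 10, 77530252 to 77565708, plus strand), went from 55.2 ± 5.95 CPM with PBS to 119 ± 7.65 with IL-1β (SD, n = 4 each), 2.16-fold higher. Flt3, which encodes a receptor of multipotent progenitors (chromosome 5, 147330741 to 147400489, minus strand), went from 52.9 ± 8.66 to 110 ± 29.6 CPM. Mycn, a Myc family gene (chromosome 12, 12936093 to 12941914, minus strand), went from 351 ± 54.4 to 153 ± 39.6 CPM, 2.33-fold lower.

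Of 10 multipotent progenitor genes, 8 rose (9 adjusted over the list alone, and 5 without IL-1β 20-day replicate 3), with a median of 1.23 (camera adjusted p = 1.27e-14, adjusted p = 0.00284 with an estimated correlation) and naming set medians of 1.05 and 1.30. Flt3 rose by 1.02 ± 0.15, Plac8 by 1.35 ± 0.13 and Cd48 by 1.10 ± 0.26; the sort selects against the products of Flt3 and Cd48. Of 30 PU.1-dependent genes, 13 rose (14 rose and 1 fell adjusted over the list alone), with a median of 0.48 (camera adjusted p = 2.17e-09, adjusted p = 0.0106 with an estimated correlation) and naming set medians of 0.23 and 0.76. Itgb2 rose by 1.11 ± 0.10, Csf3r, the receptor gene for granulocyte colony-stimulating factor, by 0.74 ± 0.12, and Itgam by 1.73 ± 0.32, while Spi1 had 0.10 ± 0.08 (adjusted p = 0.568). Of 20 granulocyte and monocyte priming genes, 7 rose and 1 fell, the same counts as adjusted over the list alone (median 0.59, naming set medians 0.147 and 0.415, camera adjusted p = 9.15e-06, adjusted p = 0.173 with an estimated correlation). Ms4a3 rose by 3.76 ± 0.34; Cebpa had -0.68 ± 0.43 and Csf1r 1.43 ± 1.03, with adjusted p of 0.416 and 0.491.

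IL-1β 20-day replicate 3 stood apart in neutrophil genes. The 13 neutrophil genes in the table summed to 1889 CPM there, 0.189% of its counts, and to between 2.56 and 9.69 CPM in the other 13 libraries. The neutrophil list had a median of 4.40 over 9 tested genes (camera adjusted p = 0.0909), with Lcn2 called, and -0.61 without this library. Without it the PU.1-dependent median was 0.30, the multipotent progenitor median 1.02, the granulocyte and monocyte priming median 0.10, the lymphoid priming median 0.15 and the erythroid median 0.03, each still called with the preset correlation, and 763 genes were called.

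**Figure D2:**
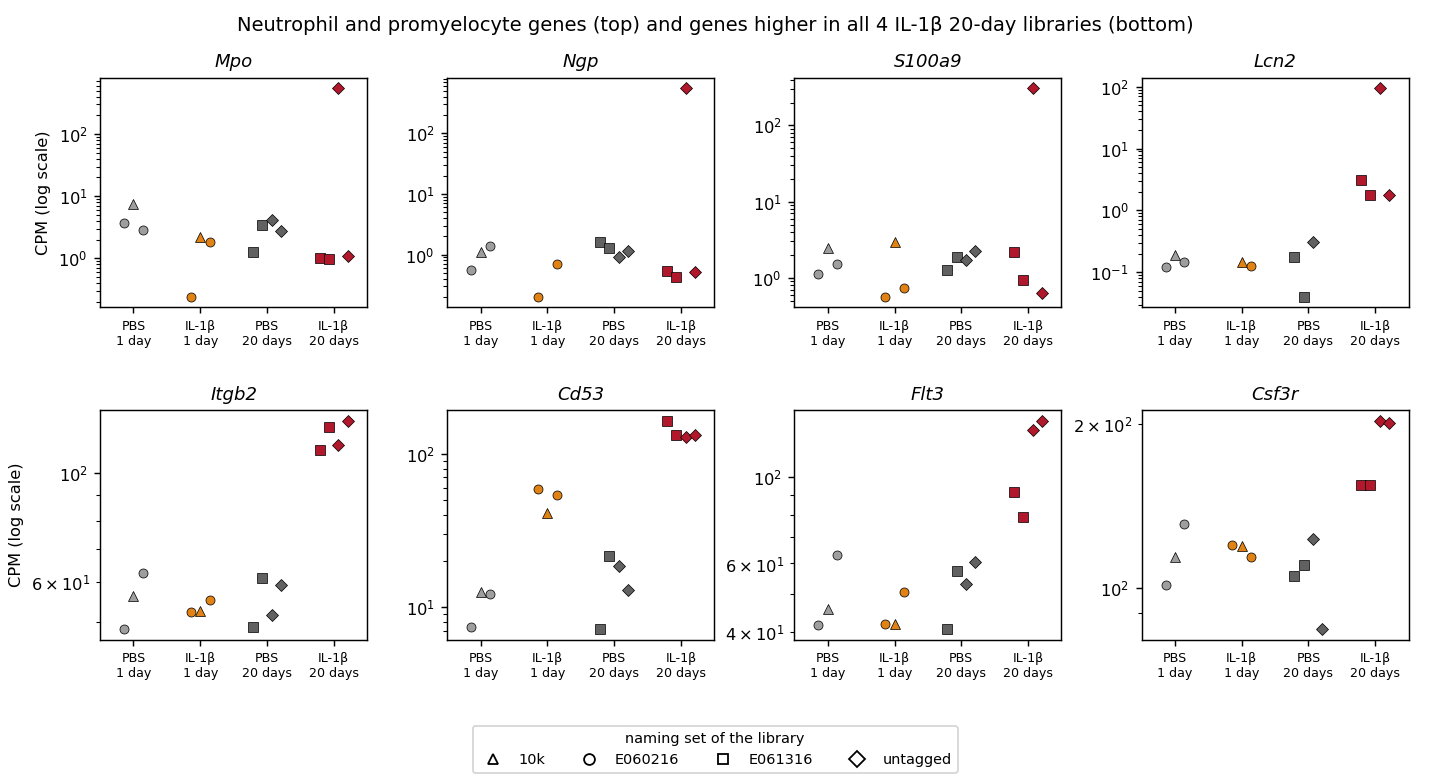
CPM per library on a log scale for Mpo, Ngp, S100a9 and Lcn2 (top) and Itgb2, Cd53, Flt3 and Csf3r (bottom) in the 4 groups; libraries at 0 counts are not drawn. IL-1β 20-day replicate 3 had 541 CPM of Mpo, while the other 3 libraries of its group had 0.971 to 1.10.

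Of 33 genes of Myc and ribosome biogenesis, 25 fell (32 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 1.84e-33, adjusted p = 0.0315 with an estimated correlation) and naming set medians of -0.38 and -0.58. Mycn fell by 1.22 ± 0.09, Myc by 0.42 ± 0.08, and Gnl3, a nucleolar gene, by 0.68 ± 0.09. Translation factors were lower as a list (4 of 42 fell, 10 adjusted over the list alone, median -0.17, naming set medians -0.00913 and -0.35, camera adjusted p = 1.38e-06, adjusted p = 0.347 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.20 over 79 genes with none called (camera adjusted p = 2.2e-07, adjusted p = 0.491 with an estimated correlation), but 0.09 in E061316 and -0.45 in the untagged set, and the call was lost without PBS 20-day replicate 4 (adjusted p = 0.126). Oxidative phosphorylation genes had a median of -0.13 over 74 with none called (camera adjusted p = 0.0037, adjusted p = 0.642 with an estimated correlation), 0.22 in E061316 and -0.44 in the untagged set, and 0.03 without PBS 20-day replicate 4.

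Of 32 mitosis genes, 23 rose (29 adjusted over the list alone, median 0.45, camera adjusted p = 2.45e-19, adjusted p = 0.0967 with an estimated correlation), with Aurka at 0.54 ± 0.10. The DNA replication list was not called (1 of 37 rose, median -0.06, camera adjusted p = 0.248) and had naming set medians of 0.21 and -0.30. Among 12 genes of G1 cyclins and kinases, 1 rose and 2 fell (2 and 2 adjusted over the list alone, median -0.15, camera adjusted p = 0.0441, adjusted p = 0.429 with an estimated correlation), with naming set medians of 0.09 and -0.33: Cdk6 rose by 0.92 ± 0.08, and Ccnd1 and Ccnd2 fell by 1.92 ± 0.18 and 1.09 ± 0.10. Of 23 adhesion and migration genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 1.25e-10, adjusted p = 0.0091 with an estimated correlation). Cd53, a tetraspanin gene (chromosome 3, 106759921 to 106790149, minus strand), rose 9.27-fold, from 15.0 ± 6.31 to 139 ± 16.6 CPM. Of 22 megakaryocyte and platelet genes, 10 rose and 2 fell (13 and 2 adjusted over the list alone, median 0.42, camera adjusted p = 1.38e-06, adjusted p = 0.182 with an estimated correlation); Selp rose by 1.35 ± 0.16 and Thbs1 fell by 2.34 ± 0.35. Of 15 erythroid genes, 6 rose and 1 fell (7 and 3 adjusted over the list alone, median 0.57, camera adjusted p = 5.51e-05, adjusted p = 0.0463 with an estimated correlation), with naming set medians of -0.03 and 0.56. Hbb-bt, a beta globin gene, rose 8.64-fold, while its neighbour Hbb-bs, chosen after its values were seen, fell by 1.68 ± 0.36. Of 7 sort marker genes, 3 rose (3 adjusted over the list alone, median 0.28, camera adjusted p = 6.45e-06, adjusted p = 0.0106 with an estimated correlation), including Slamf1 (0.81 ± 0.12). This list pools genes whose products the sort selects for, such as Slamf1, with Flt3 and Cd48, whose products it selects against. It also holds Cd34 and Cd27, which the stated sort does not use, so its median has no single reading. Of 14 lymphoid priming genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.30, naming set medians 0.12 and 1.01, camera adjusted p = 0.00498, adjusted p = 0.0967 with an estimated correlation).

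Of 19 antigen presentation genes, 5 fell (7 adjusted over the list alone, median -0.20, naming set medians -0.07 and -0.41, camera adjusted p = 1.53e-06, adjusted p = 0.182 with an estimated correlation), including H2-Aa (-1.40 ± 0.17) and Cd74 (-1.51 ± 0.19). Of 35 interferon response genes, 6 fell (11 adjusted over the list alone, median -0.22, naming set medians -0.06 and -0.24, camera adjusted p = 0.00245, adjusted p = 0.24 with an estimated correlation). Of 21 unfolded protein response genes, 5 fell (8 fell and 1 rose adjusted over the list alone, median -0.24, naming set medians -0.13 and -0.33, camera adjusted p = 5.51e-05, adjusted p = 0.234 with an estimated correlation), including Xbp1 (-0.56 ± 0.08). Of 24 immediate early and heat shock genes, 3 fell (5 adjusted over the list alone, median -0.34, camera adjusted p = 0.00241, adjusted p = 0.392 with an estimated correlation), but the untagged set had a median of 0.16, and the call was lost without PBS 20-day replicate 1 (adjusted p = 0.0574). Of 11 macrophage genes, 4 fell (5 adjusted over the list alone, median -1.17, camera adjusted p = 0.00055, adjusted p = 0.216 with an estimated correlation). Of 10 mitochondrial transcripts none was called (median -0.34, camera adjusted p = 0.0177, adjusted p = 0.471 with an estimated correlation; naming set medians -0.000108 and -0.71), and the call was lost without IL-1β replicate 4 or PBS replicate 4 of the 20-day groups (adjusted p = 0.169 and 0.245).

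Of 29 genes of the NF-kB and IL-1 response, 4 rose and 2 fell (9 and 3 adjusted over the list alone, median 0.13, camera adjusted p = 0.022, adjusted p = 0.347 with an estimated correlation), with naming set medians of -0.01 and 0.38, including Nfkb1 (0.46 ± 0.07) and Socs3 (1.80 ± 0.28). Of 24 genes of IL-1 receptor signalling, 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.0162, adjusted p = 0.392 with an estimated correlation), with naming set medians of -0.02 and 0.15. Il1r1 rose by 2.21 ± 0.26, and Il1rap, its coreceptor gene, had 0.00 ± 0.22 (adjusted p = 1). Stem cell identity genes were not called as a list: 4 rose and 6 fell, with a median of 0.03 and a mean of -0.04. Socs2 fell by 1.37 ± 0.12. Of 3 T and NK cell genes measured, 1 rose, and of 4 mast cell and basophil genes, 3 rose, with a median of 2.71, including Fcer1a (1.79 ± 0.38).

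In all, 1154 of 15466 genes changed after 20 days, 609 higher and 545 lower, each with the same sign in both naming sets. As at 1 day, the shared sign is nearly given by the calling. By at least 2-fold, 165 rose and 115 fell. Among the 6 largest increases, Capn6, Sema3d, Gna14 and Ccdc151 were at least 28-fold, 22.9-fold, 20.6-fold and 15.8-fold higher against 3 counts over the PBS group, Dntt was 60.6-fold higher (95% counting interval 20.4 to 296), and Lcn2 had 7.22 ± 1.40, with 94.1 CPM in replicate 3. In Lcn2 this replicate stood far from the other libraries of its group, so the Lcn2 fold rests largely on 1 library. Without IL-1β replicate 3, which holds 142 of the 188 Dntt counts, Dntt was 19-fold higher (95% counting interval 6.1 to 95.4). Among the 6 largest decreases, Nckap5, Gli2 and Ubd were at least 47.2-fold, 20.3-fold and 10-fold lower against 3 counts over the IL-1β group, Ccdc177 was 23.8-fold lower (95% counting interval 6.22 to 202), and Nov and Gbp11 fell by 5.05 ± 0.99 and 4.39 ± 0.93. Without the library with most of its counts, the fold was at least 16.3 for Capn6 (without IL-1β replicate 1) and 11.1 for Gli2 (without PBS replicate 4). It was 15.4 for Ccdc177 (95% counting interval 3.8 to 134, without PBS replicate 1). The leave-out fits ended the call in 13 of 14 for Ccdc177 (adjusted p up to 0.144), 9 for Ubd, 6 for Nckap5, 2 for Gli2, 2 for Lcn2, 1 for Dntt, 1 for Gbp11, 7 of the 11 that tested Gna14 and 3 of the 11 that tested Sema3d. None ended it for Capn6, Nov or, in 12 fits, Ccdc151. The count was 763, 648 and 705 without IL-1β 20-day replicates 3, 4 and 1, 525 without the naming set term, and 571 and 409 in the E061316 and untagged sets alone.

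**Figure D3:**
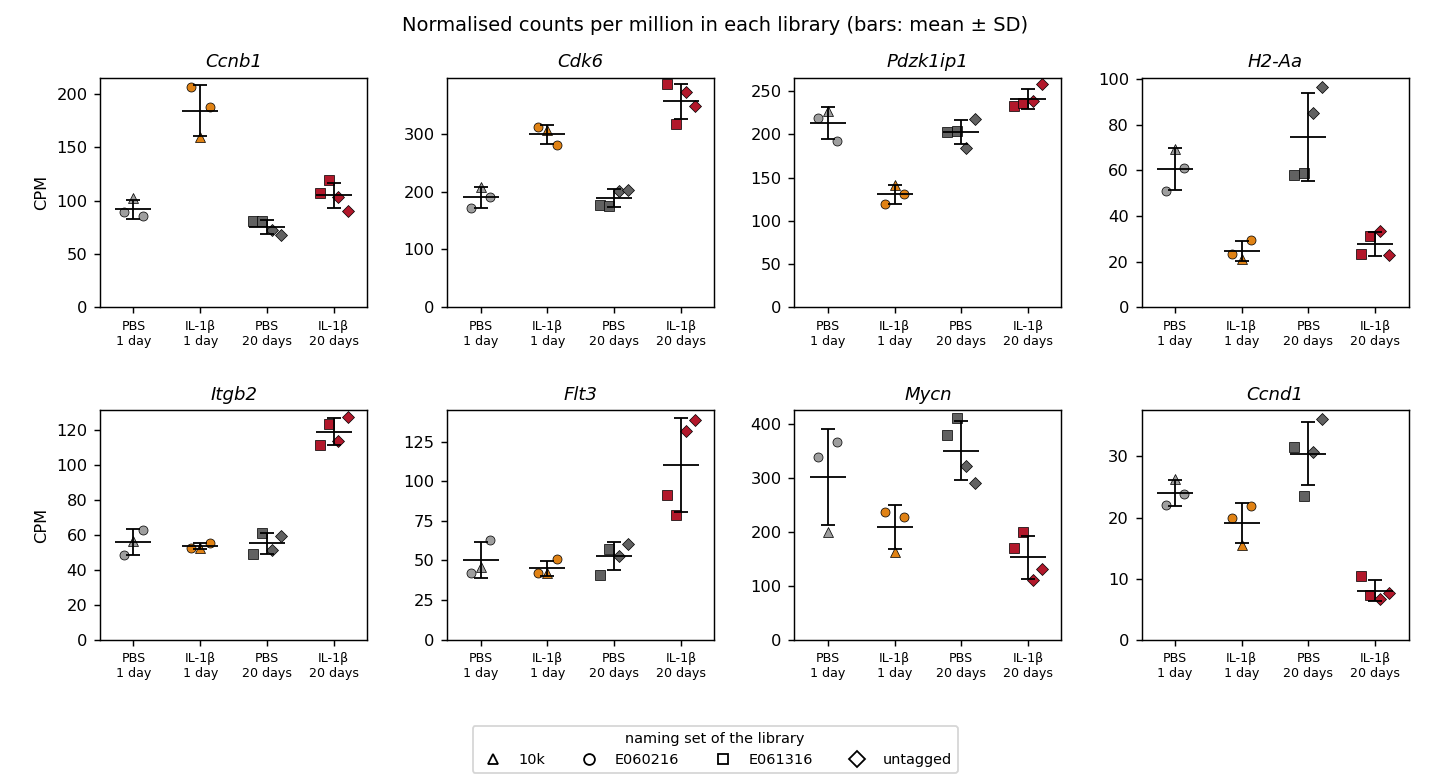
CPM per library with mean ± SD for Ccnb1, Cdk6, Pdzk1ip1, H2-Aa, Itgb2, Flt3, Mycn and Ccnd1 in the 4 groups. Mean Itgb2 was 119 CPM in the IL-1β 20-day group and 53.4 in the IL-1β 1-day group.

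The comparison of the 20-day with the 1-day effect asks which responses differ with duration. The durations hold different naming sets, so a difference between durations cannot be told apart from one between naming sets. Socs2, which encodes a suppressor of cytokine signalling, went from 33.7 ± 1.09 to 47.1 ± 1.11 CPM at 1 day (n = 3) and from 39.1 ± 2.12 to 15.3 ± 2.58 at 20 days (n = 4), a difference in log2 fold change of -1.85 ± 0.18 (edgeR adjusted p = 0.000656). H2-Ob, which encodes a chain of an MHC class II modulator, fell at 1 day and rose at 20 days, with a difference of 1.79 ± 0.20. Spic (1.88 ± 0.25), Ccl9 (2.61 ± 0.36), Pdzk1ip1 (0.96 ± 0.12) and Itgb2 (1.17 ± 0.16) were also higher at 20 days relative to 1 day. In all, 331 genes differed, 178 with a higher and 153 with a lower effect at 20 days. This balance depended on the fit. It was 20 higher and 3 lower with the replicate label as a block, 92 and 186 in the E-tagged sets alone, and 238 and 366 without IL-1β 20-day replicate 2.

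The lists of PU.1-dependent genes (3 of 30 called higher, 8 adjusted over the list alone, median difference 0.54, camera adjusted p = 1.8e-08, adjusted p = 0.0347 with an estimated correlation) and multipotent progenitor genes (3 of 10 called higher, 6 adjusted over the list alone, median 1.14, camera adjusted p = 8.3e-07, adjusted p = 0.0347 with an estimated correlation) had higher effects at 20 days. DNA replication genes had a lower one: 8 of 37 were called (35 adjusted over the list alone, median -0.67, camera adjusted p = 7.27e-27, adjusted p = 0.113 with an estimated correlation). Of 33 Myc and ribosome biogenesis genes, 11 were called lower (27 adjusted over the list alone, median -0.58, camera adjusted p = 5.56e-24, adjusted p = 0.0809 with an estimated correlation). Mitosis genes had a median of -0.44 (2 of 32 called lower, 18 adjusted over the list alone, camera adjusted p = 2.04e-14, adjusted p = 0.124 with an estimated correlation). The count of 331 was 23 without the naming set term and ranged from 34 without IL-1β 1-day replicate 1 to 604 without IL-1β 20-day replicate 2.

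The 1-day and 20-day comparisons share no libraries, but both come from 1 fit that shares each gene's dispersion. They shared 108 higher genes, against 15.3 if independent (7.05 times, Fisher's exact test, p = 2.92e-62), and 78 lower genes, against 9.97 (7.82 times, p = 3.97e-48). Genes of small dispersion are called more readily in both, and genes are not independent units. The Fisher p-values therefore do not measure agreement between independent experiments. Tgfbi, Vldlr and Cd53 were higher, and H2-Aa, Gbp4 and Thbs1 lower, at both durations. Across all 15466 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.126 and a Spearman rho of 0.116. Another 16 genes were called in opposite directions, 15 of them lower and then higher.

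PBS at 20 days and PBS at 1 day were compared to see the background between durations. No gene was called by edgeR (676 at an unadjusted p under 0.05), none by limma-voom, and 10 lower by DESeq2. The durations hold different naming sets, so the naming set and the duration cannot be told apart in this comparison.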

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

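All tests of explanations here, and the recounts over splits that keep the naming sets balanced, were chosen after the results were seen; the recounts over all splits of the libraries were planned. By Dixon's ratio of gap to range a library stood far from the others in 10 of 210 pairs of a gene taken by the rule and a 20-day group, in 6 of 38 pairs of a gene chosen after its values were seen, and in 4 of 60 pairs of a list and a group. Chance sets a library apart in about 1 in 20 groups of this size, but the genes were picked by their values, so their tally is not weighed against that rate. Of these, 14 fell on IL-1β 20-day replicate 3, among them the 6 of the genes chosen afterwards.

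In that library Mpo stood at 541 CPM, Ngp at 551, S100a9 at 306, Ltf at 300, S100a8 at 245, Camp at 167, Elane at 149, Lcn2 at 94.1, Spi1 at 132, Rhag at 35.6, Dntt at 6.16 and Prom1 at 4.69. Its mean log2 CPM was 6.42 for the neutrophil list and 5.76 for the megakaryocyte and platelet list. Without this library the 20-day median log2 fold change of the megakaryocyte and platelet list was 0.51, against 0.42 with it. The library thus did not raise that list's median. IL-1β 20-day replicate 2 stood apart in the macrophage list (-0.092) and the stroma and endothelium list (0.53), and replicate 1 in Cd53 (164 CPM). PBS 20-day replicate 3 stood apart in Prom1 (1.56 CPM) and Dntt (0.101 CPM), and replicate 4 in Gli2 (1.49 CPM).

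The effect of IL-1β differed between 20 days and 1 day, by the interaction in camera at the preset correlation, for 22 lists. Median differences in log2 fold change were 0.44 for the NF-kB and IL-1 response, 0.54 for PU.1-dependent genes, 0.66 for granulocyte and monocyte priming, 0.26 for stem cell identity, 0.47 for megakaryocyte and platelet, 0.36 for erythroid and 0.43 for lymphoid priming genes. They were -0.44 for mitosis, -0.67 for DNA replication, 0.38 for quiescence, -0.59 for G1 cyclins, -0.58 for Myc and ribosome biogenesis, -0.20 for ribosomal proteins and -0.31 for translation factors. They were 0.20 for the interferon response, -0.40 for oxidative phosphorylation, -0.21 for glycolysis, -0.24 for the unfolded protein response, 0.26 for adhesion, 1.02 for stroma and endothelium, 1.14 for multipotent progenitors and 0.28 for sort markers. With an estimated correlation the call held for PU.1-dependent and multipotent progenitor genes, adjusted p = 0.0347 each. At the preset correlation 17 of the 22 lists stayed called in each of the 14 leave-out fits. Calls ended for stroma and endothelium (0.158 without PBS 1-day replicate 1, adjusted p = 0.0694, and without the PBS or the IL-1β library of 10k, adjusted p = 0.0503 and 0.0542) and for erythroid genes (0.228 and 0.236 without the same 10k libraries; 0.0717 and 0.083). They ended for lymphoid priming without IL-1β 20-day replicates 3 and 1 or PBS 20-day replicate 4 (0.25, 0.116 and 0.176; 0.0538, 0.0678 and 0.0607). They ended without PBS or IL-1β 1-day replicate 1 for glycolysis (-0.146 and -0.176; 0.107 and 0.0608) and the unfolded protein response (-0.186 and -0.155; 0.107 and 0.0893). They also ended for glycolysis without IL-1β 20-day replicate 3 (-0.162; 0.0547) and for the unfolded protein response without IL-1β 20-day replicate 4 (-0.192; 0.0534). While still called, granulocyte and monocyte priming fell to 0.132 and erythroid genes to 0.0203 without IL-1β 20-day replicate 3, lymphoid priming to 0.112 without PBS 1-day replicate 1, the interferon response to 0.0947 without IL-1β 1-day replicate 1, and ribosomal proteins moved to -0.0891 without PBS 20-day replicate 4. Also still called, megakaryocyte and platelet genes fell to 0.279 without IL-1β 20-day replicate 4. Quiescence genes fell to 0.232 without PBS 20-day replicate 4, and sort markers to 0.169 without PBS 20-day replicate 1.

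By edgeR's interaction test 38 of the 124 genes followed differed between durations. Without the naming set term, and likewise with the replicate label as a block, 23 genes were called in all, so these 38 calls cannot all hold there. Higher effects at 20 days, in log2, were found for Pdzk1ip1 (0.96), H2-T23 (0.62), Ebi3 (1.18), Traf1 (1.25), Gp9 (1.08), Hbb-bt (1.5), Irak3 (0.72), Itgb2 (1.17), Cd52 (1.57), Ms4a3 (2.42), Plac8 (1.30), Rab27b (0.58), Rhag (2.19), Aqp1 (1.01), Flt3 (1.18), Ccng2 (0.70), Mmp14 (1.09), Itgb7 (1.39), Slamf1 (0.82), H2-Ob (1.79), Spic (1.88), Ccl9 (2.61), Pcp4l1 (0.71), Dhrs3 (1.43), Ms4a6c (1.01) and Ms4a6b (0.89). Lower effects were found for Rrm1 (-0.66), Cdc6 (-0.74), Bcl3 (-1.17), Mycn (-0.72), Socs2 (-1.85), Ccnd1 (-1.59), Ppan (-0.61), Gnl3 (-0.63), Hsph1 (-0.84) and Mcm5 (-0.87). The fitted values of Ccdc151 (12.8) and Ccdc177 (-7.92) depend on the prior count, since a group had 0 to 3 counts, and the call ended in 6 of the 12 and 11 of the 14 leave-out fits that tested them. Of the 38 calls, 9 held in each of the 14 fits. Those that ended in at least 10 of 14 include Mmp14 (12), Cd52 (11), Ccng2 (11), H2-T23 (10), Hbb-bt (10), Rab27b (10) and Gnl3 (10).

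Myeloid and multipotent progenitor genes were higher after 20 days. RNA of neutrophils and promyelocytes in replicate 3 is argued against as the whole cause: without it the PU.1-dependent median was 0.30 and 9 of 13 called members were still called, although the median had been 0.48, and 5 of 10 multipotent progenitor genes were called higher, against 8 with it. A GC content or exon length trend is argued against likewise, with a median of 0.56 after correction. Progenitors that express Mpo inside the gate are argued against by a mean of 1.02 CPM of Mpo in the other 3 IL-1β libraries, against 2.89 ± 1.21 with PBS (SD, n = 4). Progenitors without Mpo inside the gate, and a change within the stem cells under the treatment, stay open and were not tested. The 4 mast cell and basophil genes measured had a median of 2.71 at 20 days, and whether RNA of such cells shares in the pattern was not tested.

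Hbb-bt was higher under IL-1β without other globin genes. RNA of erythroid cells as the whole cause would bring Hba-a1, which was at most 0.304 CPM in the IL-1β 20-day libraries and 1.26 ± 1.07 with PBS (SD, n = 4; highest 2.68), although Rhag and Aqp1 rose (1.87 and 0.89) and reads that Hba-a1 shares with Hba-a2 may be lost. Reads of Hbb-bs assigned to Hbb-bt stay open: Hbb-bs had 2.84 CPM in the PBS libraries against a gain of 103 CPM for Hbb-bt, but a low count of Hbb-bs is what such an assignment would leave. A regulation of Hbb-bt by the treatment stays open and was not tested.

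MHC class II genes were lower under IL-1β, in 4 genes chosen after their values were seen (H2-Aa, H2-Ab1, H2-Eb1 and Cd74), with 2 called at 1 day and 4 at 20 days, while H2-Ob rose at 20 days (0.91) and of 23 H2 genes 6 fell and 2 rose there. Less macrophage RNA stays open: across the 7 PBS libraries class II and macrophage levels ran opposite ways, with Pearson r = -0.768 (exact permutation p = 0.0423, adjusted 0.0423), Spearman rho = -0.821 (exact permutation p = 0.0341, adjusted 0.0423; 2 relations), and of the 3 naming sets with 2 PBS libraries they did so in 2, while both levels moved the same way in the untagged set. Against it as the whole cause, the 3 PBS libraries with a macrophage level no higher than the highest with IL-1β (1.4) had class II levels of at least 6.07, above the highest with IL-1β (5.29), but the libraries so compared are of different naming sets, r was -0.275 without the 2 libraries farthest from the median, and within naming sets the mean log2 change was -1.19 for macrophage and -1.11 for class II genes (10k -0.413 and -1.08, E060216 -1.54 and -0.793, E061316 -1.84 and -0.887, untagged -0.955 and -1.69). The permutation p-values come from moving libraries across naming sets and durations, so they do not measure a relation within a set. A GC content or exon length trend is argued against, with medians of -0.99 and -1.40 after correction (-0.96 and -1.41 before). A shift between subsets within the sort gate and a response of the stem cells stay open and were not tested.

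Treatment labels were reassigned among the libraries. The 10 splits at 1 day are too few for a share under 0.05: the real split called 672 genes and 12 lists, the highest other 1 gene and 14 lists, and 1 split reached the gene count and 3 the list count. At 20 days 1 of 34 splits reached 1154 genes and the highest other called 5; the 18 splits that keep both naming sets balanced are too few for a share under 0.05 (1 reached it, the highest other called 1). For the number of lists chance cannot be excluded, as 4 of 34 splits reached 22 and the highest other had 25. The other splits called a median of 9 lists at 1 day and 12 at 20 days, against a median of 0 genes at each. Camera at the preset correlation thus also calls lists under reassigned labels. The 20-day split that follows the naming set cannot be fitted with the term and called 13 genes in the fit of group means. For the difference between durations, 1 of 100 drawn splits was at 331 genes with the highest other at 150, and 1 of 100 at 22 lists with the highest other at 20. Of 100 drawn from the 216 splits that keep the naming sets balanced, 3 reached 331 genes, the real split among them. Another called 1231, with the 1-day labels swapped and the 20-day labels kept, where the effects add. The last called 739, with the 1-day labels kept and the 20-day labels mixed. For lists, only the real split reached 22, with the highest other at 19. Reassigned labels also break the IL-1β effect within each duration, so these recounts cannot exclude chance for a difference between durations. Between the PBS groups the real split called 0 genes in edgeR, which each of the 35 splits reaches by construction, so the recount decides nothing; the real split had 676 genes at an unadjusted p under 0.05, 10 by DESeq2 and 0 by limma-voom.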

How the results depend on the processing

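The GC and length correction and the E-tagged sets alone were chosen after seeing the data; the other alternatives were planned. Main counts were 672 genes at 1 day, 1154 at 20 days and 331 for the difference. In that order they were 290, 525 and 23 without the naming set term, 1398, 1804 and 1182 with DESeq2's Wald test, 1187, 1750 and 831 at an adjusted p of 0.1, and 128, 280 and 96 with a log2 fold change of at least 1. With the libraries of the duration alone there were 1200 and 750 genes, in E060216 alone 1820, and in E061316 and the untagged set alone 571 and 409; these could not be had for the difference. With the GC and length correction there were 1018 at 1 day and 720 for the difference, with the E-tagged sets alone 1767 at 1 day, and with the stricter filter 556 for the difference. DESeq2 called 10 genes between the PBS groups. Called lists numbered 1, 6 and 2 with an estimated correlation, and 7 at 1 day with fry, against 12, 22 and 22. Shared genes at an adjusted p of 0.1 were 169 higher and 149 lower. Other scalings, limma-voom and no filter kept the counts within 1.5 times, and moved the median of all genes by under 0.1. The pseudocounts planned for normalised values were not run, since the values are counts; edgeR's prior count enters the fitted values of genes near 0. The cause of these changes was not tested, apart from the fewer libraries or the changed threshold.

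With the replicate label as a block there were 383, 672 and 23 genes. With naming set and group means removed, deviations of libraries with the same number correlated across genes at -0.0422 in E060216, 0.00832 in the untagged set and 0.139 in E061316, so the numbers do not pair the libraries throughout.

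Leaving out each library in turn gave 228 to 1244 genes at 1 day, 648 to 1156 at 20 days, 34 to 604 for the difference, 0 to 0 between the PBS groups, and 11 to 13, 16 to 26 and 20 to 24 lists. The 1-day count was 228 to 331 without a library of E060216, 562 and 578 without those of 10k, and 574 to 1244 without a 20-day library. The 20-day count was 648 to 1140 without a 20-day library and 917 to 1156 without a 1-day library. The difference was 135, 95, 122 and 604 genes without IL-1β 20-day replicates 3, 4, 1 and 2, 134 without PBS 20-day replicate 3, 38 and 78 without PBS 1-day replicates 2 and 1, and 34 and 40 without IL-1β 1-day replicates 1 and 2. Of the followed genes called in the full fit, 30 of 58 at 1 day, 66 of 89 at 20 days and 9 of 38 for the difference stayed called in each of the 14 fits, and Ccdc151 at 20 days in the 12 that tested it. Those lost include Cdkn1c (10 of 14 fits), H2-Eb1 (5), Mycn (4), Egr1 (4) and Ccnd2 (1) at 1 day, and Cd48 (4), Lcn2 (2), Dntt (1) and Hbb-bs (1) at 20 days.

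With the E-tagged sets alone ribosomal proteins (0.0828, adjusted p = 0.00865) and oxidative phosphorylation (0.21, adjusted p = 1.96e-10) were called higher at 20 days instead of lower, and DNA replication, not called before, was called higher (0.20, adjusted p = 4.94e-06). The NF-kB list (-0.0565, adjusted p = 0.99) and mitochondrial transcripts (-0.0146, 0.917) reversed in median or test direction without a call, as did the difference for ribosomal proteins (0.0482, 0.255). The difference for immediate early genes, not called before, was called lower (-0.13, 0.0377). Leaving out 1 library, oxidative phosphorylation at 20 days ran from -0.217 without PBS replicate 1 to 0.0251 without PBS replicate 4. The cause was not tested. At 20 days the NF-kB list was lost without IL-1β replicates 3 and 4 or PBS replicates 3 and 4 (adjusted p = 0.0613, 0.0866, 0.0656 and 0.132), G1 cyclins without the same libraries (0.0722, 0.243, 0.125 and 0.0832), IL-1 receptor signalling without PBS replicate 4 (0.147), and oxidative phosphorylation without IL-1β replicates 3 and 4 (0.174 and 0.243). Genes near the floor of 3 counts are limited by depth.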

Other observations

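The gene families in this part were chosen after the values were seen, so the counts are given with no test. Guanylate-binding proteins, which are induced by interferon in host defence, were called lower in 6 of 10 measured at 1 day and 7 of 10 at 20 days. Gbp2, Gbp3 and Gbp7 are also members of the interferon response list, so the family is not a separate observation from that list. Similar members of a family may share reads, so these are not counts of independent genes. Gbp4 fell by 2.31 ± 0.32 and 2.22 ± 0.27 on the log2 scale, and Gbp6 by 1.78 ± 0.22 and 1.83 ± 0.19. Of 7 Ms4a genes, which encode membrane proteins of leukocytes, 5 were called higher at 20 days, including Ms4a6c (1.46 ± 0.14) and Ms4a6b (0.80 ± 0.12).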
